A study of Mus musculus with 4 samples.

How the data were processed

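Single cells sorted as cancer-associated fibroblasts were profiled from 4 untreated orthotopic APTKA colon tumours of female C57BL6J mice, 1 plate of 384 wells per tumour, by the SORT-seq protocol with CEL-Seq2 libraries, per the labels. The labels give 1 group, so the 4 tumours were treated as its replicates; the gate of the sort, the mice per tumour and any treatment group are not given in the sources used here. Per the submitters' processing notes, BWA and the mm10 assembly were used; versions, the counting program and the annotation are not given in the sources used here. The deposited values are expected counts (estimated transcripts per gene and well, corrected for UMI saturation): all values above 0 equal the correction of a whole number of UMIs out of 4096 possible ones to within 0.00486, in 16305 genes. Values were rounded to whole counts for count tests, and whole UMIs recovered by undoing the correction were used in an alternative. The sequencing run given in the names of the deposited files differs between tumour 1 and tumours 2 to 4, so the run cannot be separated from tumour 1.

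Spike-ins were left out of all totals. A well was kept with at least 1000 transcripts and at most 30% mitochondrial transcripts. Of 130, 255, 250 and 218 wells with enough transcripts in tumours 1 to 4, 87, 5, 7 and 14 were over the mitochondrial limit, which left 43, 250, 243 and 204 cells with medians of 1855, 2331, 2751 and 2930.5 genes. No cell was removed as a doublet, because each well was meant to hold 1 cell; Scrublet called 6, 2 and 2 cells in tumours 2, 3 and 4 and gave no value in tumour 1. The ribosomal RNA gene Rn45s made up 3.55, 23.1, 10.6 and 10.1% of the transcripts of the plates. Whole plates differed by a chi-square per gene of 4.83 to 40.2, so no 2 plates were copies of each other.

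Counts were scaled to the median total and log-transformed, the 1500 most variable genes within tumours were chosen with all test-list genes left out, and values were centred within each tumour. Cells were clustered on 20 principal components and 15 neighbours by the Leiden method (scanpy 1.11.5, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3), first all cells at resolution 1 (15 clusters), then the fibroblast-like cells alone at resolution 0.8 (9 clusters). A cluster took the name of a class when at least 3 of its markers were found in at least 25% of cells with a log2 fold of at least 1 over the other cells and the mean log2 fold of the class's markers was above 0; of several, the class with the largest share of its markers was taken. Clusters with no other class were called fibroblast-like when at least 3 fibroblast markers were found in most cells. The name was withheld where another class had more markers among the 10 leading genes, or where the cells were shallow and no own marker led. The marker lists were fixed first, but this rule was set after the clusters had been seen. The condition on the mean left cluster 2 unnamed (3.33, 9.91, 10.4 and 13.0% of fibroblast-like cells in tumours 1 to 4), which carried the myCAF markers Col8a1, Thbs2 and Tnc. The condition on leading genes left cluster 6 unnamed (0, 6.13, 9.95 and 9.32%), whose leading genes held Slpi, a marker of antigen-presenting CAFs. The name withheld there was telocyte: its 5 telocyte markers were a larger share of their list than its 7 myCAF markers. Clusters 2 and 6 were each counted as myCAF-like in added alternatives, which for cluster 6 was not the rule's own candidate. In cluster 7, 2 myCAF markers (Spp1 and Tagln) and 2 markers of the fixed cycling list (Cdk1 and Ccnb2) were among the leading genes, so it kept the name. Cenpa, Ccna2, Stmn1 and Racgap1, cell cycle genes outside that list, were among them too. With these on the list, the rule would have named the cluster cycling in place of myCAF-like. In cluster 4 no iCAF marker was among the leading genes. Shares were given per tumour with Clopper-Pearson intervals.

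Counts were summed per tumour and class, for each class with at least 10 cells in the tumour. They were compared by edgeR quasi-likelihood tests (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr and the tumour as a block, and p-values were adjusted by Benjamini and Hochberg over the genes that were not clustering features. The sums held 302051 to 1124950 transcripts for iCAF-like against myCAF-like cells. Clusters 1, 2, 3 and 6 were each compared with all other fibroblast-like cells; the sums held 110477 to 2546450, 126124 to 2755220, 180131 to 2346500 and 146695 to 2734640 transcripts, with 808, 1657, 643 and 1686 genes at an unadjusted p under 0.05. Cycling cells did not form a cluster of their own name. Gene lists were fixed before the data were examined, together with the tests, the named gene Il1r1 and the first set of alternatives below. They were tested by camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation, and by fry, adjusted over the 17 lists; for iCAF-like against myCAF-like cells fry called 0 lists by direction (lowest adjusted p 0.175) and 3 by its mixed test of change in either direction (lowest adjusted p 0.00181). By direction fry called 1, 5, 1 and 4 lists for clusters 1, 2, 3 and 6. Genes were named by rule: Il1r1, up to 2 members of each list with the largest absolute fold changes, 4 higher and 4 lower genes outside the lists, and 3 higher and 3 lower genes for each other class, all past the threshold and changed the same way in every tumour compared; further members that passed are named without values and were chosen after their values were seen. Where a class had 0 counts, the fold was computed against a floor of 3 counts over the class and is given as "at least". This floor bounds the class with 0 counts only. It leaves out the counting error of the other class and the spread between tumours. Where a class had 1 to 3 counts, the ratio was given with its 95% counting interval. The median of each list was the same with such genes at their bound. Levels are means over tumours with their SD, in transcripts per 10000. Coordinates are from GENCODE vM21 (GRCm38), in which 71 of 73 genes were matched by symbol.

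The tests were tested on simulated data with the depths and spread of each comparison, with 100 genes changed by each fold. The changed genes were drawn only from genes above a minimum mean count per sum. Recovery of tested genes with fewer counts was not measured. Of genes changed 2-fold and 4-fold, 27 and 90% were recovered for iCAF-like against myCAF-like cells (5 of 123 calls false), 54 and 90% for cluster 1 (6 of 158), 19 and 72% for cluster 2 (1 of 97), 35 and 86% for cluster 3 (7 of 132) and 19 and 73% for cluster 6 (0 of 95). Cells simulated without states were drawn from each tumour's mean profile, with no added spread between cells, and clustered with the same settings. The naming rule was skipped: of the clusters large enough, those farthest apart in marker level were compared, over 3 tumours. This gave 0 higher and 0 lower genes of 4811 (edgeR, 228 at an unadjusted p under 0.05) and 0 of 17 lists. It says little about false calls from clustering and testing the same real cells.

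Alternatives set at that point were DESeq2 (1.42.0) and its size factors, no count filter, no block, each tumour left out, count splitting, cells ranked by marker score, cells thinned to 3000 transcripts with shallower cells left out (524 of the 604 fibroblast-like cells were deep enough), other limits on depth and mitochondrial share, no centring, other numbers of variable genes, other resolutions, doublets left out, an estimated correlation and whole UMIs. Added after the data had been seen were ribosomal RNA left out, 3 other seeds, clustering without tumour 1 or on whole UMIs, clusters 2 or 6 counted as myCAF-like, at least 5 cells per sum, and a joint fit of all classes (19 sums, 9 residual degrees of freedom). A few single-gene results are not reported here.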

Results

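Fibroblasts make up much of the stroma of colorectal tumours, and the title of this series concerns their inflammatory state. RNA was read from single cells sorted as cancer-associated fibroblasts (CAFs) out of 4 untreated colon tumours, which were grown in the colon of female C57BL6J mice from a line that the labels name APTKA. There was 1 group, so tumours 1 to 4 were its replicates and every comparison was made between classes of cells from the same tumours. The labels do not say whether the tumours came from separate mice. Each tumour was sorted into 1 plate of 384 wells with 1 cell per well (SORT-seq, which counts mRNA molecules by unique molecular identifiers, UMIs). The plates held 612734, 3165550, 2805112 and 2727191 transcripts in tumours 1, 2, 3 and 4. Of 1536 wells, 740 cells were kept (43, 250, 243 and 204), with medians of 5552, 8516, 8108 and 9474.5 transcripts per cell. Tumour 1 was the poorest plate: spike-in RNA made up 44.0% of its transcripts (5.54 to 8.59% in the other tumours), and the median mitochondrial share of its kept cells was 14.4% (5.25 to 6.14%).

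The sort was mostly fibroblasts in all 4 tumours. Clusters that carried fibroblast markers such as the collagen genes Col1a1 and Col1a2, met no other cell type's rule and kept the name held 604 of the 740 cells. Their share was 69.8% (95% Clopper-Pearson interval 53.9 to 82.8), 84.8% (79.7 to 89.0), 82.7% (77.4 to 87.3) and 78.9% (72.7 to 84.3) in tumours 1 to 4, a mean of 79.1 ± 6.65% (SD, n = 4). Other mesenchymal cells were also present. Smooth-muscle-like cells (35 cells, 4.73%) carried Myh11, the smooth muscle myosin heavy chain, at 63.1 ± 16.0 transcripts per 10000 (n = 4 tumours). Pericyte-like cells (32 cells, 4.32%) carried Rgs5, a regulator of G protein signalling typical of pericytes, at 9.10 ± 2.07 and the receptor Notch3 at 8.49 ± 0.505 (n = 3). Cells like the interstitial cells of Cajal, the pacemakers of gut muscle (17 cells, 2.30%), carried the receptor Kit at 47.5 ± 10.5 and the chloride channel Ano1 at 35.6 ± 15.6 (n = 2). A cluster of 52 cells (7.03%) met the marker condition for fibroblast-like cells, but the name was withheld because markers of red cells were among its leading genes. These cells are therefore not in the share above. The cluster was led by the beta-globin gene Beta-s and by Alas2, the first enzyme of haem synthesis in red cells (74.8 ± 34.9, n = 3), at 0.307 of the tumours' median depth. No cluster was named epithelial, endothelial, immune, glial or mesothelial. The pericyte-like cluster also met the marker conditions for endothelial cells with Emcn, Esam and Flt1 (mean log2 fold of the endothelial markers 0.78). Pericyte markers were the larger share of their list.

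The 604 fibroblast-like cells formed 9 clusters. Clusters 0 (93 cells) and 4 (68 cells) met the rule for inflammatory CAFs, called iCAF-like here. Cluster 0 carried Il6 and Cxcl1, which encode an interleukin and a chemokine, at higher levels than the other cells, and cluster 4 carried the chemokine gene Ccl2 and the progenitor marker Cd34. Cluster 7 (40 cells) met the rule for contractile, matrix-making CAFs, called myCAF-like here, with 10 myCAF and 8 cycling markers. Its 10 leading genes held the actin-binding gene Tagln and the matrix phosphoprotein gene Spp1, and also the cell cycle genes Cdk1, Ccnb2, Ccna2, Cenpa, Stmn1 and Racgap1. Had all of these been on the fixed marker list, the rule would have named the cluster cycling in place of myCAF-like. Cycling markers stood further above the other cells (mean log2 fold 2.52) than myCAF markers did (1.66), so a comparison with this class is also one with cycling cells. Il6 stood at 5.25 ± 4.16 transcripts per 10000 in cluster 0 (n = 3), 2.46 ± 0.595 in cluster 4 (n = 3) and 0.206 ± 0.244 in cluster 7 (n = 2), while Tnc, a matrix glycoprotein of wound stroma, stood at 20.8 ± 7.18 in cluster 7. Cluster 5 (25 cells) carried markers of telocytes, the subepithelial cells that signal to the crypts, and also 7 myCAF markers. Clusters 1, 2, 3, 6 and 8 met no rule; cluster 6 shared 7 myCAF and 5 telocyte markers, and 29 of the 33 cells of cluster 8 came from tumour 3.

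By the naming rule, iCAF-like cells outnumbered myCAF-like cells in each of the 4 tumours. iCAF-like cells made up 16.7% (5.64 to 34.7), 26.9% (21 to 33.4), 23.4% (17.7 to 29.9) and 32.3% (25.2 to 40.1) of the fibroblast-like cells in tumours 1 to 4 (mean 24.8 ± 6.55%, n = 4). myCAF-like cells made up 9.43% (5.86 to 14.2), 2.49% (0.813 to 5.71) and 9.32% (5.31 to 14.9) in tumours 2 to 4. None was found among the 30 cells of tumour 1 (mean 5.31 ± 4.80%). These shares depend on the clustering: over the other settings the mean iCAF-like share lay between 10.1 and 36.5%, and in 4 settings no cluster met the myCAF rule. They also depend on the naming, and so does the order of the classes. Clusters 5 and 6, each with 7 myCAF markers, and cluster 2, with 3, were not counted as myCAF-like.

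**Figure D1:**
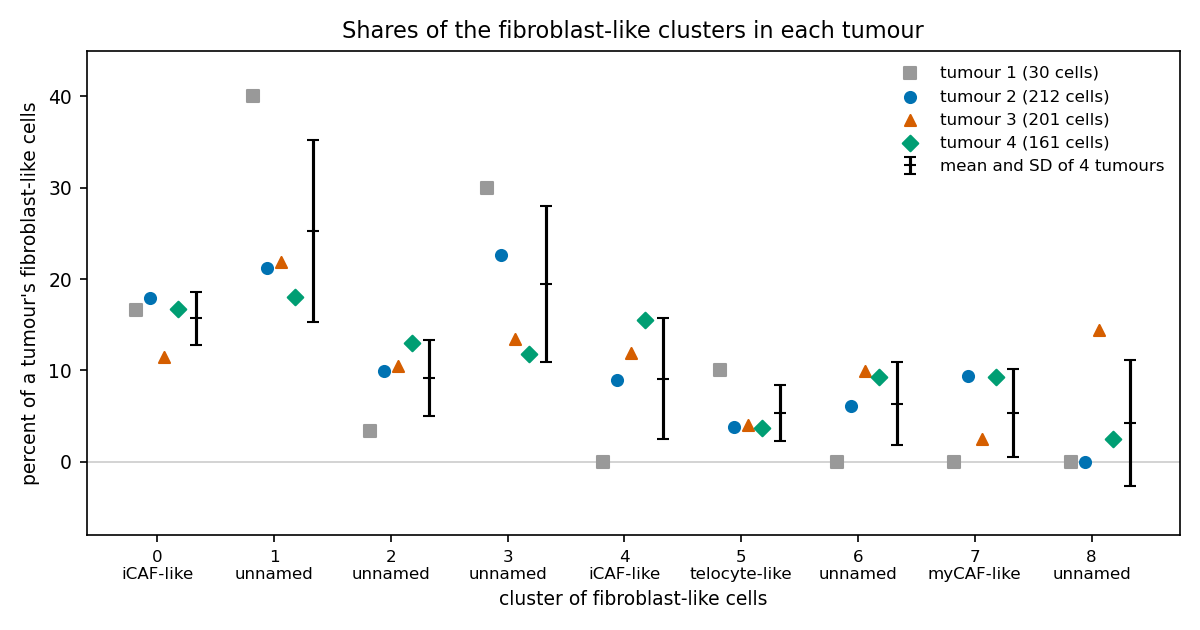
Percent of each tumour's fibroblast-like cells (vertical axis) in clusters 0 to 8 (horizontal axis), with 1 point per tumour and the mean with SD of 4 tumours. Clusters 0 and 4 together reached a mean of 24.8% and cluster 7 a mean of 5.31%.

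Between iCAF-like and myCAF-like cells of the same tumours, 408 genes were higher in the former and 249 lower, of 6697 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05; 1410 at an unadjusted p under 0.05). C3, the central complement component, stood at 42.3 ± 3.32 transcripts per 10000 against 3.90 ± 2.99 (n = 2 tumours, log2 fold change 3.71, SE 0.32, adjusted p = 1.06e-06, edgeR quasi-likelihood). Cd55, which protects cells from complement, stood at 4.01 ± 1.52 against 0.178 ± 0.0290 (log2 fold change 4.49), and Igfbp4, a secreted binder of insulin-like growth factors, at 54.6 ± 5.72 against 14.4 ± 3.43 (2.03). On the other side, Actn1, which cross-links actin filaments, and Fblim1, an adaptor of cell-matrix adhesions, were lower (-1.71 and -2.14). The test rested on tumours 2 and 4, the tumours with at least 10 cells of each class (109 iCAF-like and 35 myCAF-like cells), with 1 residual degree of freedom. The counts were 110 and 34 with DESeq2, 256 and 151 without the tumours as blocks and 435 and 305 in a joint fit of all classes. Leaving out tumour 2 or 4 left 1 myCAF-like sum, so those results come from that joint fit and are given below. The counts were 75 and 28 with 3000 variable genes and 67 and 15 in clusters built on whole UMIs. In the last 2 settings 79 of 140 and 78 of 130 fitted lower genes kept their direction, and 6 and 3 were called again.

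The iCAF-like class was named by inflammatory markers such as Il6, Cxcl1 and Ccl2, so higher levels of related lists were favoured by the naming. Keeping list genes out of the clustering features does not remove this. Of the lists tied to inflammation, complement differed most: 9 of 10 measured genes were higher and none lower, also with p-values adjusted over the list alone. Its median log2 fold change was 2.68 (camera adjusted p = 1.09e-17, or 0.511 with an estimated correlation). For this contrast the correlation was estimated on 1 residual degree of freedom. Its adjusted p-values therefore neither support nor count against a list. Among cytokines and chemokines, 7 of 14 were higher and none lower (8 and 0 over the list alone, median 1.29, adjusted p = 6.95e-06, 0.511 as adjusted p with an estimated correlation), led by Cxcl2, a chemokine for neutrophils (4.27; 1.25 ± 0.349 against 0.0552 ± 0.0780 per 10000), and Tnfsf13b, the B cell survival factor BAFF (3.63). In the JAK-STAT3 list 8 of 16 were higher and none lower (9 and 0, median 0.90, adjusted p = 1.49e-05, adjusted p = 0.511 with an estimated correlation), among them the acute-phase transcription factor Cebpd (2.49), the kinase Pim1 (2.12) and the pathway's own inhibitor Socs3. NF-kB targets had 8 of 18 higher and none lower (10 and 0, median 0.80, adjusted p = 2.69e-05, adjusted p = 0.726 with an estimated correlation). They included Tnfaip3 (2.32), Nfkbia and Zc3h12a, which restrain this pathway, beside the adhesion genes Icam1 (2.25) and Vcam1. The interferon and MHC class I list was called on 3 of 26 genes, with none lower (3 and 0 over the list alone, median 0.43, adjusted p = 0.0462, adjusted p = 0.536 with an estimated correlation): Ifitm3, Ifit1 (2.68) and Rsad2, an antiviral enzyme with 38 counts against 2 (ratio 8.17, 95% counting interval 2.11 to 69.9). The list of dissociation stress was higher in the same cells (13 of 20 genes higher, adjusted p = 6.45e-11, adjusted p = 0.511 with an estimated correlation).

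The receptor of interleukin 1, Il1r1, was higher in iCAF-like cells by the planned test: 1.34 ± 0.509 against 0.659 ± 0.183 transcripts per 10000 (log2 fold change 1.09, SE 0.30, adjusted p = 0.0277, edgeR quasi-likelihood). The gene lies on the plus strand of chromosome 1 at 40225080 to 40317257 (mouse assembly GRCm38). Of 10 measured genes of interleukin 1 signalling, 3 were higher and none lower (4 and 0 over the list alone, median 0.71, camera adjusted p = 0.00999, adjusted p = 0.511 with an estimated correlation). The other two were brakes on the pathway: Il1r2, a decoy receptor that binds the cytokine without signalling (160 counts against 2, ratio 34.4, interval 9.36 to 286), and Irak3, which inhibits the receptor's kinases (1.94). Within the iCAF-like cells, Il1r2 came from cluster 4, at 1.71 ± 0.0924 per 10000 against 0.0581 ± 0.0307 in cluster 0 (n = 3). The call of Il1r1 held in 11 of 28 alternatives (log2 fold change 0.96 to 1.23). It was lost without the tumours as blocks (1.04, adjusted p = 0.201) and with DESeq2 (1.09, adjusted p = 0.633), where the fold stayed about as large, and the fold change was -0.35 in clusters that also took cells from 500 transcripts and -0.033 with cluster 6 counted as myCAF-like.

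Matrix and contractile genes were split between the classes. The myCAF-like class was named by contractile and matrix markers, so lower actin genes in iCAF-like cells were favoured by the naming. Of 29 actin and adhesion genes, 10 were lower and none higher (17 lower and 1 higher over the list alone, median -0.68, camera adjusted p = 1.68e-06, adjusted p = 0.511 with an estimated correlation), among them Myh9, Flna, Itgb1 and Actb. Collagens and their processing enzymes went both ways, with 3 of 21 higher and 5 lower (3 and 7 over the list alone, median -0.26, adjusted p = 0.0447, adjusted p = 0.726 with an estimated correlation). Col11a1, a fibrillar collagen of tumour stroma (-3.52), Loxl3, a collagen cross-linking oxidase (-2.33), Col5a3, P4ha1 and Fkbp10 were lower, while Loxl1, Pcolce and Adamts2, which process fibrillar collagen and elastin outside the cell, were higher. Basement membrane genes had 6 of 13 higher and 1 lower (7 and 1, median 0.73, adjusted p = 0.00961, adjusted p = 0.689 with an estimated correlation): Col4a1 (1.49) and Col4a2 (1.45), the main collagen IV chains, were higher with Nid1, Lama2, Lama4 and Lamb2, and Col15a1 was lower. The list of TGF-beta response was not called (3 of 22 higher, 6 lower, 5 and 6 over the list alone, median -0.06, adjusted p = 0.510). Of 29 other settings, 5 called it lower and 2 higher. Its ligand Tgfb1 was lower (-2.90) and Tgfbr3, a co-receptor that can hold the ligand back, was higher (3.62). YAP targets were not called either (2 of 9 higher, none lower, 2 and 1, median 0.37, adjusted p = 0.749), although Amotl2 (1.04) and Cyr61 (0.89) were higher.

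Of secreted WNT and BMP factors, 10 of 19 genes were higher and 3 lower (12 and 3 over the list alone, median 1.61, adjusted p = 6.58e-05, adjusted p = 0.511 with an estimated correlation). The higher genes included antagonists of WNT or BMP signals (Sfrp1, Sfrp2, Sfrp4, Grem1, and Chrdl1 with 53 counts against 1, ratio 22.8, interval 3.92 to 916), with Bmp4, Fgf7, Fgf10 and Igf1. The WNT amplifier Rspo1 was at least 4.87-fold higher (34 counts against 0, floor of 3 counts over the class), while Nrg1, the WNT antagonist Dkk2 and Wnt2 were lower. Glycolysis and hypoxia genes were lower as a list (2 of 17 higher, 6 lower, 2 and 8, median -0.73, adjusted p = 0.0462, adjusted p = 0.763 with an estimated correlation): the lactate exporter Slc16a3 (-2.65), the glucose transporter Slc2a1, Pkm, Pgam1, Pgk1 and Gapdh were lower, and the hypoxia-induced peptide gene Adm (3.47) and Ndrg1 were higher. Lists for senescence (4 of 21 higher, 5 lower, 4 and 7, median -0.30, adjusted p = 0.749), p53 targets (1 of 12 higher, 2 lower, 1 and 2, median 0.16, mean -0.42, adjusted p = 0.510) and lipid and retinoid genes (2 of 15 higher, 2 lower, 2 and 2, median -0.33, mean 0.18, adjusted p = 0.510) were not called. Igfbp6 was higher (2.13), Plk2, a stress-induced kinase, was lower (-1.51), and Pmaip1, which promotes cell death, had 1 count against 18 (ratio 41.9 toward myCAF-like cells, interval 6.61 to 1745). Aldh1a1, which makes retinoic acid, was at least 8.17-fold higher, and Stra6, a retinol transporter, was lower (-4.01). Of the 17 lists, 12 were called, 9 higher and 3 lower, and 0 with an estimated correlation. With 1 residual degree of freedom the estimates ran from -0.07 to 1, so that 0 was nearly fixed by the design. Leaving out tumour 2 or 4 left 1 myCAF-like sum, and a joint fit of all classes was used. Without tumour 4, the lists of cytokines, NF-kB targets, interleukin 1 signalling, basement membrane and interferon were no longer called. Without tumour 2, WNT and BMP factors, collagen and glycolysis were not. In the joint fit of all 19 sums, chosen after the data were seen, 4 lists were called with an estimated correlation too. These were complement (camera adjusted p = 0.00711), dissociation stress (0.0139), JAK-STAT3 (0.0207) and actin and adhesion (0.0207).

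**Figure D2:**
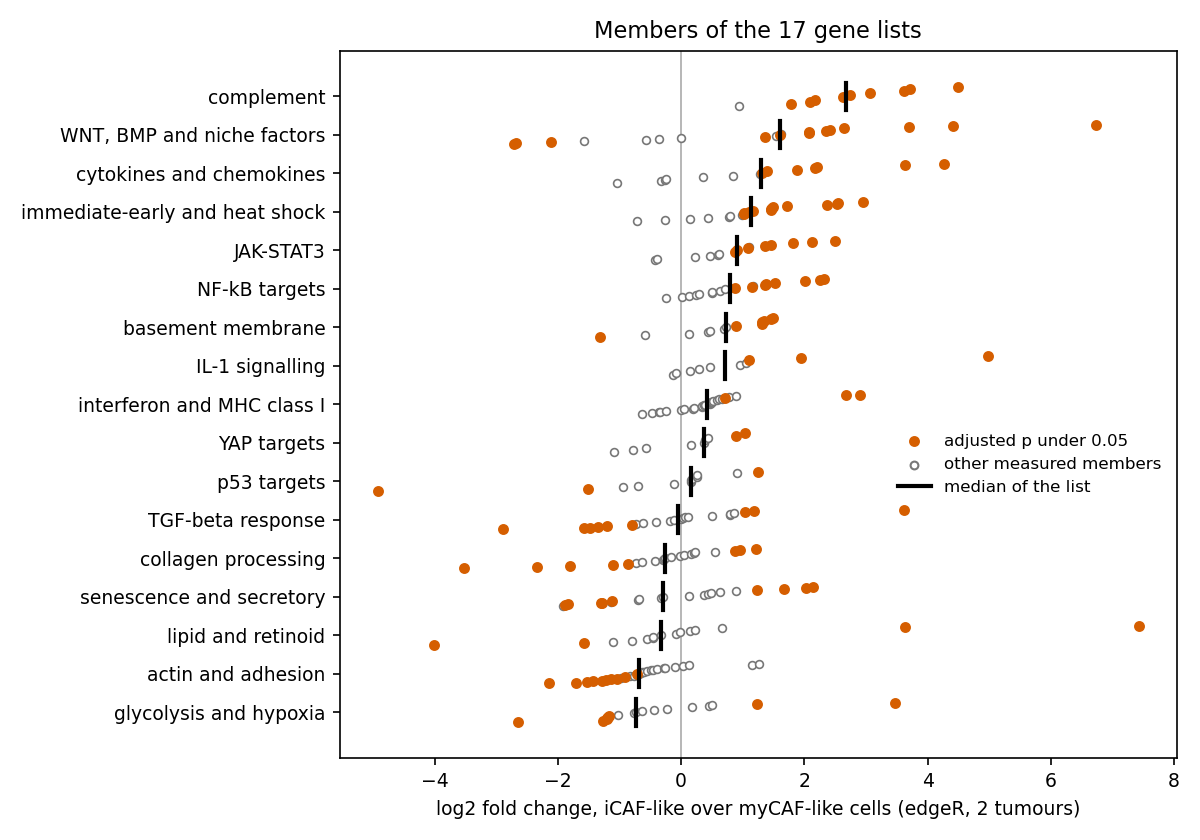
Log2 fold change, iCAF-like over myCAF-like cells (horizontal axis), of the measured members of 17 gene lists (vertical axis): orange points passed an adjusted p of 0.05, open points did not, and black bars are medians. Complement sits highest with a median of 2.68 and glycolysis lowest with -0.73; genes with 0 counts in a class are drawn at their fitted value, which is no bound.

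Outside the lists, genes were named by their fitted fold changes, which do not rank genes with 0 counts in a class. The higher genes in iCAF-like cells were 4932411N23Rik (at least 9.46-fold higher), Cys1 (at least 4.15-fold), Tmem170b (at least 4.01-fold) and Tnxb, a tenascin of loose connective tissue (log2 fold change 5.12). The lower genes were the phagocytic receptor gene Megf10 (at least 13.2-fold lower), Eva1a (at least 11.6-fold lower), and the mitosis genes Cdca8 (1 count against 46, ratio 107 toward myCAF-like cells, interval 18.3 to 4318) and Cdkn3 (1 against 33, ratio 76.8, interval 12.9 to 3124). In tumour 3, whose 5 myCAF-like cells were too few for the test, 96.1% of the 408 higher and 74.7% of the 249 lower genes went the same way, against 67.3% of all 7466 fitted genes on the higher side. Of 43 named genes 37 went the same way there; Col11a1, Plk2, Ifit1, Rspo1 and Megf10 went the other way and Pmaip1 showed no difference. In at least 1 other grouping of the cells the direction turned for Cxcl2, Loxl3, Col4a1, Col4a2, Cyr61 and Aldh1a1.

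The classes also differed in cell cycle and in the list of dissociation stress, while positional genes differed within the iCAF-like class. At least 2 cycling markers were found in 55% of the cells of cluster 7, against 7.53% in cluster 0 and 13.2% in cluster 4 (31.3, 1.14 and 1.49% of the 32, 88 and 67 cells that were deep enough to be thinned to 3000 transcripts). The list of dissociation stress, the immediate-early genes that rise while tissue is digested, was higher in iCAF-like cells: 13 of 20 genes were higher and none lower (16 and 1 over the list alone, median 1.13, camera adjusted p = 6.45e-11, adjusted p = 0.511 with an estimated correlation), led by Atf3 (2.95) and Dusp1 (2.55). Median transcripts per cell were 15598 in cluster 0, 16510 in cluster 4 and 22742 in cluster 7. Positional genes, here and below, were summed over tumours with at least 5 cells of a cluster. They were not kept out of the clustering features as the test lists were, so their differences between clusters may be partly built in. Tumour 1 held 5 cells of cluster 0 and tumour 3 held 5 of cluster 7. Hoxc genes, which mark position along the body axis, summed to 0.104 ± 0.153 per 10000 in cluster 0 (n = 4 tumours), 1.46 ± 0.700 in cluster 4 (n = 3) and 0.966 ± 0.494 in cluster 7 (n = 3). A list of gut mesenchyme genes drawn up after the data were seen (Foxf1, Tcf21 and others) summed to 3.02 ± 1.05, 0.457 ± 0.145 and 1.01 ± 0.773 in the same clusters. The iCAF-like class thus joined cells that differed in these genes.

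In cluster 6, Mmp13, a collagenase that acts on fibrillar collagen, stood at 184 ± 32.9 transcripts per 10000 against 0.706 ± 0.0877 in the other fibroblast-like cells (n = 3 tumours, log2 fold change 7.97, adjusted p = 3.55e-20, edgeR quasi-likelihood), and Mmp10, a stromelysin, at 91.3 ± 24.5 against 0.461 ± 0.160 (7.61). The WNT ligand gene Wnt7b was at least 128-fold higher. Ptgis, which makes prostacyclin, Clip4, a microtubule-binding protein, and Pard3b, a polarity protein, were at least 22.2-, 11.5- and 7.80-fold lower. In all, 381 genes were higher and 508 lower of 7763 (48 against 526 cells). The counts were 246 and 304 without tumour 3, 231 and 311 without tumour 4 and 213 and 227 with DESeq2.

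In cluster 2 (63 cells in tumours 2 to 4, against 511) the higher genes named by the same rule were Art4, an ADP-ribosyltransferase (at least 80.7-fold higher), Grik4, a kainate receptor subunit (16 counts against 1, ratio 215, interval 33.4 to 9024), and Ntsr1, the neurotensin receptor (13 against 2, ratio 87.4, interval 19.8 to 798). Serpinb1a, a protease inhibitor, the tetraspanin gene Tspan11 and the laminin gene Lama5 were at least 15.1-, 12- and 10.2-fold lower. In all, 392 genes were higher and 541 lower of 7793. The counts were 211 and 346 without tumour 3, 204 and 289 without tumour 4 and 193 and 202 with DESeq2.

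Cluster 1 was the single cluster with the most cells (130 against 474, all 4 tumours). It carried Wnt4, a WNT ligand, at 3.94 ± 1.86 transcripts per 10000 against 0.298 ± 0.115 (log2 fold change 3.72, adjusted p = 7.09e-05, edgeR quasi-likelihood). Ano5 (3.68) and Adam23, an adhesion protein of the ADAM family (3.53), were also higher. Sfrp4, a secreted WNT antagonist, was lower (-5.48), as were AI607873 (1 count against 231, ratio 47.6 toward the other cells, interval 8.46 to 1889) and the glycosyltransferase gene Galnt16 (2 against 415, ratio 42.8, interval 11.8 to 354). In all, 148 genes were higher and 116 lower of 5233. Leaving out 1 tumour gave 266 and 250 (tumour 1), 55 and 42 (tumour 2), 49 and 40 (tumour 3) and 62 and 49 (tumour 4), and without the tumours as blocks 88 and 59.

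In cluster 3 (94 cells in tumours 2 to 4, against 480) Megf6 (4.86), Crispld1 (3.97) and the homeobox gene Irx5 (3.43) were higher. Mmp13 (-4.62) and Mmp10 (-4.26) were lower, because cluster 6 was among the other cells, and Slc16a3 had 1 count against 130 (ratio 17.5 toward the other cells, interval 3.09 to 698). In all, 40 genes were higher and 59 lower of 7975. These counts were 1 and 13 without tumour 3, 51 and 67 without tumour 2, 6 and 9 without the tumours as blocks, 16 and 26 with DESeq2, and 335 and 278 at Leiden resolution 0.4.

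**Figure D3:**
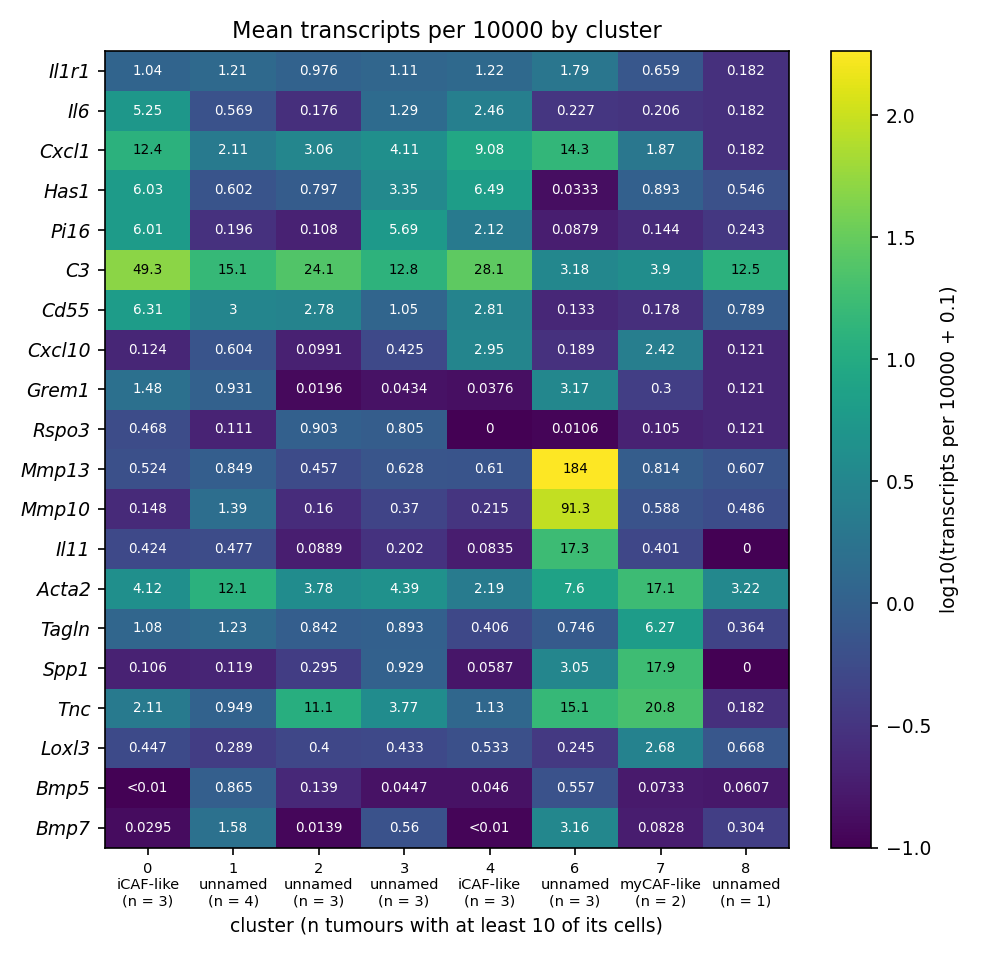
Mean transcripts per 10000 (colour, log10 scale after adding 0.1) of 20 genes (vertical axis) in each fibroblast-like cluster (horizontal axis), over the tumours with at least 10 cells of that cluster. Mmp13 (184) and Mmp10 (91.3) peak in cluster 6 and C3 is lowest in clusters 6 (3.18) and 7 (3.90); cluster 5 had no tumour with 10 cells and is not drawn.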

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

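The test on cells matched for handling stress and the tests on cycling cells were chosen after the results they concern had been seen; thinning was planned, and the splits of the samples followed a rule set beforehand, but their limit to splits that part every tumour was applied after the counts had been seen. Each quantity measured per tumour was compared between the 4 tumours by Dixon's test, and 4 of 20 exceeded its critical value; chance alone does so in about 1 in 20 groups. All were tumour 1: spike-ins made up 44.0% of its transcripts (5.54 to 8.59% in the others), the median mitochondrial share of kept cells was 14.4% (5.25 to 6.14%), 87 wells were over the mitochondrial limit (5 to 14), and cluster 5 made up 10% of its fibroblast-like cells (3.73 to 3.98%). The last share rests on 30 cells. Cells of 4 other clusters were used in no comparison: 17 Cajal-like, 32 pericyte-like, 35 smooth-muscle-like and 52 cells led by globin genes.

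The complement list was called higher in iCAF-like cells, and so was the list of dissociation stress, with Atf3 and Dusp1 among its genes (each adjusted p = 0.511 with an estimated correlation). Where iCAF-like cells were matched to the 20 and 15 myCAF-like cells of tumours 2 and 4 in that list, the complement median was 2.30 (camera adjusted p = 1.75e-14) 242 genes were higher and 89 lower, and 8 lists were called in place of 12 (interleukin 1 signalling, interferon, collagen and glycolysis were lost, adjusted p = 0.23, 0.42, 0.59 and 0.60), while the stress median went from 1.13 to 0.39. That argues against stress as the whole cause for complement, although matching was incomplete (mean scores 1.42 and 1.47 against 1.07 and 1.12). With cells thinned to 3000 transcripts, shallower cells left out, the complement median was 2.71 over the 7 genes still measured (10 before, camera adjusted p = 3.17e-07). The difference thus remained where each cell had equal weight in the sums. The classes were those of the unthinned cells, so a role of depth in forming the clusters was not tested. Position also stays open: the iCAF-like class joined cells with few and with many Hoxc transcripts. No biological explanation was tested by the design.

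The genes lower in iCAF-like cells included mitosis genes such as Cdca8 and Cdkn3, and more cells of the myCAF-like class were cycling. Without cells that held at least 2 cycling markers, 15 myCAF-like cells were left, and of the 165 lower genes that could be fitted 69.7% (62.1 to 76.6) kept a log2 fold change under -1, against 91.8% before; 162 went the same way and 46 were called. Since the interval reached below the limit set for that test, a contribution of cycling cells cannot be told apart from the contractile state with so few cells. In the other clusters, 38 cells held at least 2 cycling markers. They carried the lower genes at a median log2 ratio of 0.13 (0.03 to 0.17) over 496 others. These cells were picked on unthinned counts, and only 2 cycling markers could be fitted. After thinning to equal depth, 31.3% of the cells of cluster 7 that were deep enough held at least 2. Outside it, this left 1 cell in cluster 0, 1 in cluster 4 and 0 in clusters 1, 2, 3, 5, 6 and 8. Since few of the 38 cells may have been cycling, the test cannot tell whether the lower genes rise in any cycling cell.

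Both sums of a tumour came from the same tumour, so the real split was compared with the splits that part the sums of every tumour. These were too few for a share under 0.05: 8 splits for cluster 1, where the real split gave 264 genes and the highest other 6, and 4 splits for each of clusters 2, 3 and 6, where the real splits gave 933, 99 and 889 genes and the highest other 0. In each cluster 1 split was as large, the real one. The other splits put both sums of some tumours on the same side. The classes were also defined by clustering the same cells, which favours the real split.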

How the results depend on the processing

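Results with clusters built again on whole UMIs, with seeds 1 to 3, for tumours 2 to 4 alone or with ribosomal RNA left out, clusters 2 or 6 counted as myCAF-like, at least 5 cells per sum and the joint fit come from tests chosen after the results had been seen; the others were planned. Leaving out a tumour that was not in a comparison moved nothing there, so such values (8 for main results, 102 for named genes) are not counted. Among the main results 147 alternatives gave the same outcome, 44 were weaker, 1 was stronger, 9 shares moved and 2 values turned direction. For named genes, 1557 of 1576 values kept the direction, 152 lost the threshold and 19 turned. Why the values moved was not tested.

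With DESeq2, 110 genes were higher and 34 lower in iCAF-like cells, Il1r1 was at 1.09 with adjusted p = 0.633 (0.0523 to 0.968 over the alternatives that lost its call), and the other classes had 1091 genes. Without the tumours as blocks the counts were 256 and 151 and Il1r1 was at 1.04 (adjusted p = 0.201). Leaving out 1 tumour gave 1210 to 2437 genes in the other classes and mean shares of 77.1 to 82.1% fibroblast-like, 22.3 to 27.5% iCAF-like and 3.93 to 7.08% myCAF-like cells. For iCAF-like against myCAF-like cells tumours 1 and 3 were not in the test, so leaving them out left its 408 and 249 genes, 12 lists and Il1r1 (1.09) as they were. Without tumour 2 or 4 the joint fit was used, in which a lone sum is taken to vary like those of the other classes: without tumour 2, 229 and 141 genes, Il1r1 at 0.81 and 9 lists; without tumour 4, 146 and 95 genes, Il1r1 at 0.67 and 7 lists. The other classes had 1210 genes without tumour 3 and 1224 without tumour 4.

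Cells thinned to 3000 transcripts gave 129 and 76 genes, 7 lists and 851 genes in the other classes; Il1r1 did not pass the count filter there. Ranking cells by marker score put Il1r1 at 0.21, Cxcl2 at -0.63, Col4a1 at -0.47, Col4a2 at -0.48 and Aldh1a1 at -0.55, and gave no value for other classes. A limit of 500 transcripts gave 377 lower genes (of the 249, 147 were fitted and 123 kept the direction), 6 lists, an iCAF-like share of 10.1%, Il1r1 at -0.35, Cxcl2 at -2.37, Loxl3 at 1.12, Col4a1 at -0.52 and Col4a2 at -0.98. With 2000 transcripts Il1r1 was at 0.25 and Col4a2 at -0.092. With 3000 variable genes there were 75 and 28 genes, with Il1r1 at 1.16 (adjusted p = 0.755), Loxl3 at 1.11, Col4a1 at -0.00027 and Col4a2 at -0.14. Of the 249 lower genes 140 were fitted there, 79 kept the direction and 6 were called; of the 408 higher genes it was 371, 342 and 54. Resolution 0.4 gave 259 and 131 genes and an iCAF-like share of 15.7%, resolution 1.2 gave 146 lower genes, and without Scrublet doublets the adjusted p of Il1r1 (1.09) was 0.0523. With an estimated correlation 0 lists were called, in a fit with 1 residual degree of freedom. The share of myCAF-like cells was 0%, as no cluster met the rule, with 500 transcripts, without centring, with seed 2 and for tumours 2 to 4 alone, where clusters were compared by number.

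Without ribosomal RNA Il1r1 was at 0.46, Col4a1 at -0.11 and Col4a2 at -0.29, and the iCAF-like share was 14.2%; it was 31.5% with seed 1 and 36.5% with seed 3. Il1r1 was at 1.02 with seed 2, 1.01 for tumours 2 to 4 alone, 0.92 with at least 5 cells and 0.85 in the joint fit, in each case without a call. The joint fit called 4 lists with an estimated correlation. With cluster 6 counted as myCAF-like 7 lists were called, with Il1r1 at -0.033 and Cxcl2 at -0.42. With cluster 2 counted so, 177 and 71 genes were called, with Il1r1 at 0.69, Cyr61 at -0.037 and Aldh1a1 at -0.77. Clustering on whole UMIs gave 67 and 15 genes, Il1r1 at 0.88, Loxl3 at 0.36 and Aldh1a1 at -0.19. Of the 249 lower genes 130 were fitted there, 78 kept the direction and 3 were called; of the 408 higher genes it was 365, 329 and 47.

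With the preset correlation, over 29 settings, complement, dissociation stress and JAK-STAT3 were called in the same direction in 29, actin and adhesion in 28, cytokines and NF-kB targets in 26, WNT and BMP factors in 22, glycolysis in 19, basement membrane and collagen in 18 and interferon in 16. Interleukin 1 signalling was called in 20 of 28. None of these was called in the opposite direction. In each setting the classes were chosen by iCAF and myCAF markers, which favours the same direction for related lists. Of the lists not called in the main fit, TGF-beta response was called lower in 5 settings and higher in 2 (3000 variable genes, adjusted p = 0.0220, and clustering on whole UMIs, 1.55e-04), and senescence lower in 3; YAP targets, p53 targets and lipid and retinoid genes were called in none.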

Other observations

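The lists in clusters 1, 2, 3 and 6, the comparison of clusters 0 and 4 and the test on positional genes were chosen after the data had been seen. In cluster 6, the class with Mmp13 and Mmp10, complement genes were lower (7 of 10 lower, none higher, 7 and 0 over the list alone, median -1.71, camera adjusted p = 1.58e-08, adjusted p = 0.212 with an estimated correlation) and so were dissociation stress genes (17 of 20 lower, 1 higher, 17 and 1, median -1.22, adjusted p = 4.36e-10, 0.328 as adjusted p with an estimated correlation). NF-kB targets were higher there (10 of 19 higher, 2 lower, 11 and 2, median 0.67, camera adjusted p = 0.0132, or 0.364 with an estimated correlation). JAK-STAT3 genes were lower (6 of 16 lower, 1 higher, median -0.57, camera adjusted p = 0.0149, or 0.465 with an estimated correlation). Cytokines were not called (5 of 15 higher, 8 lower, camera adjusted p = 0.0741). The difference between the lists was not tested. The senescence list was called higher on 9 of 20 genes, with 5 lower (9 and 7, median -0.03, mean 1.21, adjusted p = 1.06e-09, adjusted p = 0.212 with an estimated correlation), and its median lay near 0. That list holds Mmp3, Mmp10 and Mmp13, which are leading genes of cluster 6. In cluster 1, 8 of 23 interferon and MHC class I genes were higher and none lower (11 and 0, median 0.49, adjusted p = 3.56e-04, adjusted p = 0.464 with an estimated correlation), among them Tap1, Psmb8, H2-K1, H2-D1, B2m, Gbp3 and Ifitm1. Of the 17 lists, 5, 9, 10 and 7 were called in clusters 1, 2, 3 and 6, and none with an estimated correlation (lowest adjusted p = 0.367, 0.232, 0.231 and 0.212). In cluster 3 all 10 were lower, first senescence (4 of 20 lower, none higher, 6 and 0, median -0.45, adjusted p = 4.18e-11, adjusted p = 0.231 with an estimated correlation). Cluster 6, with its Mmp genes of that list, was among the other cells for clusters 2 and 3. How far these genes moved the list there was not tested. In cluster 2, 12 of 20 senescence genes were lower and none higher (14 and 0, median -1.21, adjusted p = 1.14e-10, adjusted p = 0.232 with an estimated correlation), and 6 of 20 dissociation stress genes were higher and 1 lower (7 and 2, median 0.29, adjusted p = 0.00224, adjusted p = 0.315 with an estimated correlation). There, 11 of 16 cytokines were lower and 1 higher (12 and 2, median -3.35, adjusted p = 1.60e-07, adjusted p = 0.232 with an estimated correlation).

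The iCAF-like clusters differed from each other (88 against 68 cells in tumours 2, 3 and 4): 113 genes were higher in cluster 0 and 152 in cluster 4, of 4964 tested by edgeR (802 at an unadjusted p under 0.05). Cluster 0 carried the WNT amplifier Rspo3 (83 counts against 0), the transcription factor Gata6 (48 against 0), the BMP antagonist Grem1 (log2 fold change 5.40), Pitx1 (3.67) and Vcam1 (3.32). Cluster 4 carried the decoy receptor Il1r2 (-4.72), the oestrogen receptor Esr1 (-4.39) and the chemokine Cxcl10 (-4.35). Each went the same way in 3 of 3 tumours; the genes were chosen after their values were seen.

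Positional genes differed between the fibroblast-like clusters, which such genes may have helped to form (Hoxc10 and Tbx15 were leading genes of cluster 3 and Tcf21 of cluster 1). Hoxc genes summed to 1.62 ± 0.946 transcripts per 10000 in cluster 3, 1.46 ± 0.700 in cluster 4 and 0.966 ± 0.494 in cluster 7, and to at most 0.104 in clusters 0, 1, 2, 5, 6 and 8. The list of gut mesenchyme genes summed to 2.93 to 11.1 in those clusters and to 0.457 ± 0.145 and 1.01 ± 0.773 in clusters 4 and 7; in cluster 3 the sums of the 4 tumours ran from 0.464 to 6.59. The list of limb, trunk and skin genes, which holds the Hoxc genes, did not follow that division: it summed to 7.60 in cluster 6 and 6.11 in cluster 8, against 6.96 to 9.36 in clusters 3, 4 and 7. Single genes departed from it too, as Twist2 was highest in cluster 6 (4.33) and Gata6 in cluster 7 (0.373). In 524 thinned cells, genes of each kind that had not been looked at before were found in the same cell less often than independence would give (odds ratio over tumours 0.608, interval 0.393 to 0.942; 0.397, 0.372, 0.526 and 1.30 in tumours 1 to 4). That interval treats cells as independent and takes 1 odds ratio for all tumours, so it does not measure the spread between tumours. The odds ratio was not under 1 in tumour 4, and clusters 6 and 8 carried genes of both kinds. The test therefore does not settle whether free RNA or mixed wells played a part. It leaves open that the sort may hold fibroblasts of gut mesenchyme and of another body site. A hypothesis from the positional genes is that part of the iCAF-like and myCAF-like contrast reflects where the fibroblasts came from, which the design did not test.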
